A study of Escherichia coli with 12 samples.

How the data were processed

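Total RNA of one Escherichia coli strain, MG1655, was labelled with biotin and hybridised to Affymetrix antisense arrays, with 3 arrays at each of 4 times of growth and 12 arrays in all. Each array gives one value per probe set, a group of short probes aimed at one gene or one stretch between genes. The deposited values are intensities on a linear scale, which the authors computed with Affymetrix Microarray Analysis Suite version 5.0 (MAS5), per the series' design text and the submitters' processing notes. The target to which that software scaled each array is not given in the sources used here, and neither is the software's setting for background. Per the submitters' note, replicates 1 and 2 were hybridised to the older version of the array and their values were remapped by the authors to the probe sets of the second version, while replicate 3 was hybridised to the second version itself. Of the 7312 probe sets in the table, 3744 hold values on all 12 arrays and 3568 hold values only for replicate 3. The shared ones are 3722 gene probe sets and 22 controls. All 2886 intergenic probe sets, 59 probe sets of phage or plasmid genes and 623 gene probe sets have values for replicate 3 alone, so the planned test of intergenic probe sets over the 4 times could not be run, nor could a fit with them added.

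Probe sets were named through the b-number in their identifier and the Entrez ID of GEO's platform annotation, both looked up in a current table of reference genes. Of the 3722 gene probe sets, 3581 were named by both, 29 by the b-number alone and 60 by the Entrez ID alone. A further 31 matched several genes and 21 matched none, and these were left out. The platform annotation itself lists 1 symbol for 3135 of them, several for 546 and none for 41. The brightest probe set stood for each of 22 genes with several, of which 7 had probe sets whose mean changes from 90 to 360 min differed in sign. This left 3646 genes.

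The value tested was log2 of the deposited intensity plus 112.6, the 25th percentile of all gene probe set values. A fold change on this scale understates the change of genes with low signal. The arrays were left on their deposited scale in the main analysis. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the variance on the mean), with all 12 arrays in one fit. A moderated F test asked for any difference among the 4 times, and contrasts compared 150 with 90 min, 240 with 150 min, 360 with 240 min and 360 with 90 min. P-values were adjusted by Benjamini and Hochberg over the genes of each contrast, and an adjusted p under 0.05 counted as a change. A contrast of 240 with 90 min was added after the data were seen. Python 3.11.15 with pandas 2.3.3 read the annotation, and matplotlib 3.10.9 drew the plots.

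The main fit has no term for the replicate number, as fixed before the data were examined. The number turned out to pair the arrays. Replicates 1 and 2 share an array version, so the version alone does not account for the pairing, and its cause was not tested. A control probe set, AFFX-CreX-3, also parted the replicates. It read 8.7 to 10.4 in replicate 1, 49340 to 72716 in replicate 2 and 7903 to 10009 in replicate 3. Deviations from the mean of each time correlated across genes above 0.1 in 17 of the 18 pairs of arrays with the same number (lowest 0.08, median 0.43, highest 0.70), against -0.48 to 0.07 in the 36 pairs with different numbers, and 12 of 12 arrays correlated best with an array of their own number. Every replicate holds all 4 times. The count or p from a fit with the replicate as a block is therefore given beside the counts of changed genes, and beside the list calls that it adds or ends. The residual degrees of freedom were 8 without the block and 6 with it. The sources do not say whether arrays of one number came from one culture, or whether the replicates were separate cultures, so the p-values measure only the spread between these arrays.

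The 27 gene lists, with 108 tests over the 4 planned contrasts, were written before the data were examined, from general knowledge of Escherichia coli. They cover ribosomal proteins, translation factors and aminoacyl-tRNA synthetases, ribosome hibernation, nucleoid proteins and global regulators, RNA polymerase and DNA topology, DNA replication and cell division, RpoS-dependent stress genes, acid resistance, flagella and chemotaxis, fimbriae and curli, glycolysis, the TCA cycle, the glyoxylate shunt and acetate use, aerobic respiration and ATP synthase, anaerobic respiration and fermentation, amino acid catabolism, alternative sugar and glycerol use, purine and pyrimidine synthesis, amino acid biosynthesis, fatty acid synthesis, fatty acid degradation, iron uptake, heat shock and proteases, oxidative stress and the SOS response, cold shock proteins, phosphate and nitrogen starvation, and autoinducer-2 uptake. Each was tested with limma's camera, which compares a list with all other genes at a preset correlation of 0.01 between genes. Camera with a correlation estimated from these arrays made 0 calls at an adjusted p under 0.05 (5 at an unadjusted p under 0.05, smallest adjusted p 0.641), and limma's fry, which asks whether a list's genes move on balance one way without comparing them with other genes, made 0 (8 unadjusted, smallest adjusted p 0.102). Every call of a list below rests on the preset correlation.

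Genes named in the text follow a rule fixed before the data were examined. It takes, per contrast, the 6 largest rises and 6 largest falls among genes past the threshold whose 3 values at one time all lie above the 3 at the other and whose mean signal at the higher time is at least the median of 353. It adds the 2 or 3 members past the threshold with the largest change of each list that camera called, all 21 nucleoid proteins and global regulators, and the 5 genes with the smallest p in the F test. Since no gene passed in the contrasts of neighbouring times, rules added after the values were seen name there the genes that changed at least 2-fold in each of the 3 replicates, up to 8 per direction by the smallest of their 3 changes, and the 2 members of each called list with the largest mean change.

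The fit was run on simulated changes added to values drawn with the spread of these arrays. For 360 against 90 min, with 3646 genes and no block, it recovered 10% of the genes changed 2-fold, 64% at 4-fold, 80% at 8-fold and 98% at 16-fold, with 0 unchanged genes called. With the block, the shares were 36%, 82%, 96% and 100%, and 3 unchanged genes were called. The simulated genes were drawn independently of each other. On the real arrays genes correlate, with an estimate of 0.88 among ribosomal protein genes. The simulated counts of unchanged genes therefore do not give the rate of false calls in these data. The number of arrays limits the precision throughout. Alternatives covered quantile normalisation, scaling to one median or one 75th percentile, pseudocounts of 0, 40.3 (the 10th percentile) and 294 (the 50th percentile), filters on dim genes, the replicate block, 3 models of the variance, the mean of a gene's probe sets, a 2-fold limit, fits on 6 arrays, and leaving out each array in turn. Leaving out all of replicate 1, 2 or 3, and quantile normalisation together with the block, were added after the data were seen.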

Results

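Transcript levels of Escherichia coli MG1655, a laboratory strain here wild type for the nucleoid protein Fis, were followed on 12 Affymetrix arrays through a growth course in LB, a rich broth, at 37 °C. Saturated cultures were diluted to an OD600 of 0.05, and RNA was taken after 90 min, early in logarithmic growth, after 150 and 240 min, in its middle and late stretches, and after 360 min, as the cultures entered stationary phase. Each time has 3 replicates. The question put to the data is which transcripts change as a culture passes from fast growth into stationary phase. The arrays were not on one scale. Median gene signal lay between 313 and 352 on the arrays of replicate 1, between 322 and 426 in replicate 2 and between 162 and 216 in replicate 3. The highest gene signal of an array was 26965 to 32586 in replicate 1, 104406 to 125938 in replicate 2 and 12197 to 15768 in replicate 3. Replicates 1 and 2 were measured on an older version of the array than replicate 3, so changes within each replicate and results with the replicate as a block stand beside the main ones.

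The fis transcript was measured first, since the series names its strain by this gene. Fis (b3261) is a nucleoid-associated protein made mainly early in growth. Its signal at 90 min was 17793, 1912 and 1344 in replicates 1, 2 and 3, and at 150 min it was 6784, 1197 and 205. At 240 min it was 5516, 405 and 253, and at 360 min 388, 484.5 and 291. Between 90 and 360 min the mean fis level differed by -2.93 on the log2 scale, which is 7.59-fold lower (SE 1.09, n = 3 per time), with -5.16, -1.76 and -1.85 in the 3 replicates. This did not pass the test without a replicate block (limma, adjusted p = 0.106) and passed with it (adjusted p = 0.0122). Without the 240 min array of replicate 1 the adjusted p was 0.0452, and without its 90 min array the change was -1.80 with an adjusted p of 0.410. With the block the adjusted p was 0.0828 when all of replicate 2 was left out.

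Among the 21 nucleoid proteins and global regulators, dps rose and spoT fell between 90 and 360 min. Transcripts of dps, whose protein packs and protects the chromosome of starved cells, were 32.4-fold higher (log2 change 5.02 ± 0.93, SE, n = 3 per time, adjusted p = 0.00256). Those of spoT, for the enzyme that makes and degrades ppGpp, were 3.13-fold lower (-1.64 ± 0.49, adjusted p = 0.0431). With the replicate block, 7 of the 21 rose and 3 fell. The rises then included both subunits of integration host factor, ihfA (1.57, block adjusted p = 0.0278) and ihfB (1.37, 0.0327). The others were cbpA, for a curved-DNA-binding protein (1.16, 0.0286), rpoS, for the sigma factor of stationary phase (1.34, 0.0236), csrA (1.13, 0.0452) and arcA (1.25, 0.0187). The falls with the block were fis, spoT and hupA, a subunit of the HU protein (-1.78, 0.00377). The remaining 11 passed in neither fit, with log2 changes of -0.97 for lrp, -0.84 for hupB, -0.77 for stpA, -0.62 for crp, -0.28 for rpoD, -0.26 for hfq, -0.23 for hns, -0.23 for relA, 0.12 for dksA, 0.31 for fnr and 0.52 for cyaA. The list as a whole had a mean change of 0.15 and a median of -0.23, opposite in sign, and camera did not call it (adjusted p = 0.742).

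**Figure D1:**
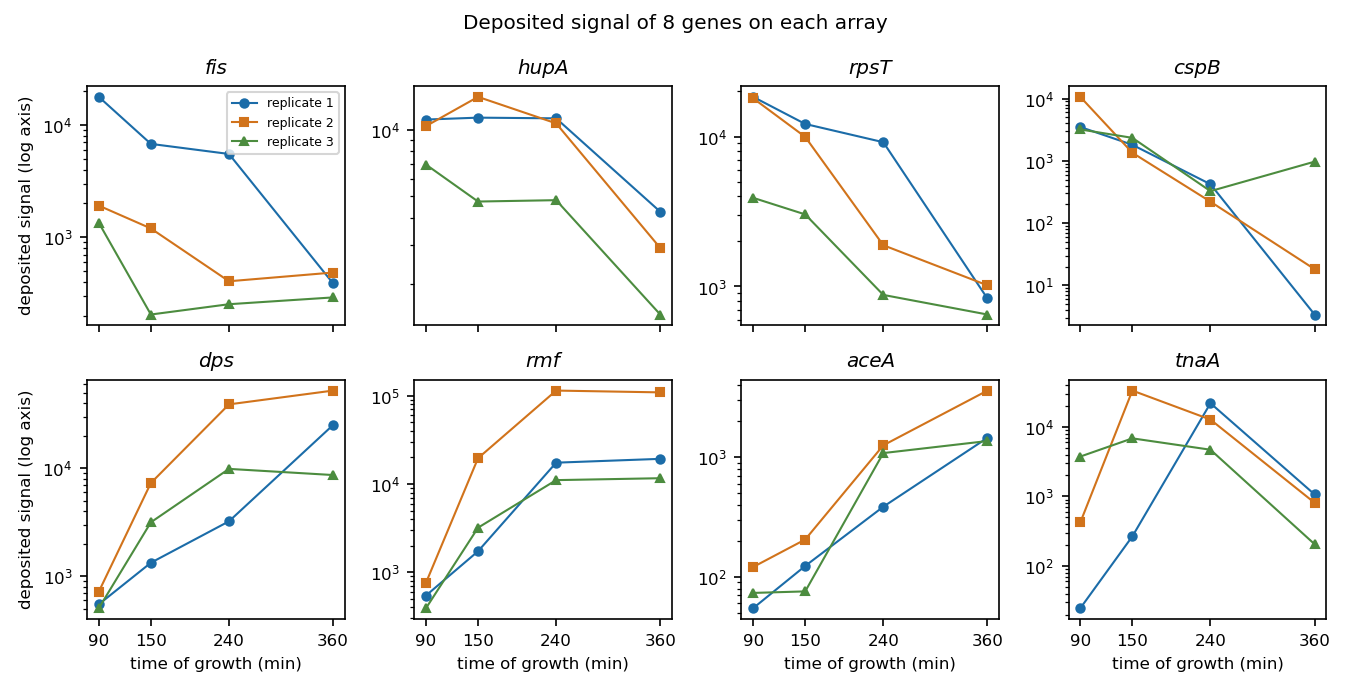
Deposited signal (log axis) against time of growth in min for 8 genes, with one line per replicate and one point per array. At 90 min fis reads 17793, 1912 and 1344 in replicates 1, 2 and 3, and at 360 min all 3 arrays lie between 291 and 484.5.

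Over the 4 times, the moderated F test called 173 of 3646 genes, and 143 of them had their highest mean at 360 min. Another 22 were highest at 90 min, 3 at 150 min and 5 at 240 min. The 5 genes with the smallest p all climbed from low signal, with an adjusted p of 0.00225 each. Mean signal went from 46.9 at 90 min to 5018 at 360 min for yohC (b2135), an inner membrane protein, and from 30.5 to 7431 for astC (b1748), an enzyme of arginine degradation. It went from 171 to 9885 for melA (b4119), the alpha-galactosidase of melibiose use, and from 55.5 to 4756 for ytfR (b4485), part of a galactofuranose transporter. For aceA (b4015), isocitrate lyase of the glyoxylate shunt, it went from 83.1 to 2134. With the replicate block 677 genes passed, all 173 among them, and their highest means fell at 90 min for 272 genes, 150 min for 66, 240 min for 44 and 360 min for 295. The count without the block was 95 without the 90 min array of replicate 2, 288 without the 240 min array of replicate 1, 63 without the 360 min array of replicate 1 and 51 without the 360 min array of replicate 2. It was 104 without replicate 1, 0 without replicate 2 and 2 without replicate 3. The count with the block was no steadier, at 69 without the 90 min array of replicate 2, 308 without the 360 min array of replicate 2, 419 without the 90 min array of replicate 1, and 427 without the 360 min array of replicate 1. It was 378 to 415 without one of the 150 min arrays or the 240 min array of replicate 3, 110 without all of replicate 3 and 0 without all of replicate 2.

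The ends of the course, 360 against 90 min, compare early stationary with early logarithmic cells. Folds and their order in this paragraph are on the tested scale, whose pseudocount understates changes of genes with low signal. On it the largest rises were in sra (b1480), a protein bound to ribosomes of stationary cells, at 51.3-fold (log2 change 5.68 ± 0.84, SE, n = 3 per time, adjusted p = 0.000896), and in astC at 50.7-fold (5.67 ± 0.78, adjusted p = 0.000866). Mean deposited signal went from 354.9 to 28921.7 for sra and from 30.5 to 7430.6 for astC. On the deposited signal astC thus rose by the larger factor. The sugar-binding protein gene ytfQ (b4227) rose 45.0-fold, the ribosome hibernation gene rmf (b0953) 44.1-fold, the protein kinase gene yeaG (b1783) 42.7-fold and the periplasmic stress gene osmY (b4376) 39.8-fold. The largest falls were in the cold shock gene cspB (b1557), 19.9-fold (-4.31 ± 0.70, adjusted p = 0.00127), and in secG (b3175), for a subunit of the protein export channel, 13.3-fold (-3.74 ± 0.85, adjusted p = 0.00923). They were followed by yceD (b1088), a gene next to rpmF, at 12.2-fold, the ribosomal protein gene rpsT (b0023) at 11.8-fold, cspG (b0990; -3.46 ± 0.80) and the cell wall endopeptidase gene mepS (b2175) at 10.8-fold. Changes of cspB were unequal between replicates, at -4.96, -6.36 and -1.61.

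In this comparison 318 of 3646 genes passed, 220 higher and 98 lower at 360 min, against 819 at an unadjusted p under 0.05. All 318 changed in one direction in all 3 replicates, and 315 changed at least 2-fold, but passing the test itself selects for both. Of all 3646 genes, 24.0% had their 3 values at one time all above the 3 at the other. With the replicate block 1008 genes passed, 484 higher and 524 lower, and these held all 318. The share of rises was 69.2% without the block and 48.0% with it. The split was 401 higher and 393 lower after quantile normalisation, 382 and 413 after scaling to one median, and 396 and 397 after scaling to one 75th percentile. Counting without a test, 219 genes rose and 215 fell at least 2-fold in each replicate, against totals of 12, 0 and 2 when the signs of replicate 1, 2 or 3 were turned. The count of 318 became 197 (155 higher, 42 lower) without the 90 min array of replicate 1, 178 (151, 27) without that of replicate 2, 141 (122, 19) without the 360 min array of replicate 1 and 194 (144, 50) without that of replicate 2. The split moved with little change in the count without the arrays of replicate 3, to 171 higher and 151 lower without that of 90 min and 345 and 40 without that of 360 min. It was 239 and 153 without the 240 min array of replicate 1. It was 130, 62 and 278 when all of replicate 1, 2 or 3 was left out. The count with the block became 524 without the 90 min array of replicate 2, 569 without the 360 min array of replicate 1, and 714, 0 and 619 when all of replicate 1, 2 or 3 was left out.

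Genes of the general stress response, which depend on the sigma factor RpoS, were the list with the largest shift from 90 to 360 min. Of 34 measured members 30 rose and none fell (33 adjusted over the list alone, and 33 with the block), and the mean log2 change was 3.22 ± 0.76 (SD over 3 replicates). Examples are osmY (5.31 ± 0.88, SE, adjusted p = 0.00137), the ribosome-tethering protein gene elaB (b2266; 5.07 ± 0.89, adjusted p = 0.00184) and dps. Camera gave the list an adjusted p of 1.33e-25, which became an adjusted p of 0.641 with an estimated correlation. Ribosome hibernation genes had a mean change of 2.76 ± 0.71, and 2 of 5 rose, sra and rmf (2 adjusted over the list alone, 3 with the block). Fatty acid degradation genes had a mean change of 1.70 ± 0.47, with 5 of 8 risen (6 adjusted over the list alone, 6 with the block), among them fadB (2.73 ± 0.59, adjusted p = 0.00699), fadH (2.59 ± 0.50, adjusted p = 0.00346) and fadE (2.55 ± 0.56, adjusted p = 0.0072). Acid resistance genes had a mean change of 0.91 ± 0.24, with 5 of 19 risen (8 adjusted over the list alone, 8 with the block), led by the periplasmic chaperone hdeA (3.08 ± 0.66, adjusted p = 0.00628), slp (2.45 ± 0.42, adjusted p = 0.0018) and the glutamate decarboxylase gadB (2.39 ± 0.45, adjusted p = 0.00296). Camera's adjusted p was 0.00275 for hibernation, 0.000362 for fatty acid degradation and 0.000758 for acid resistance. For each of these lists the adjusted p was 0.641 with an estimated correlation.

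Lists of central carbon use were called upward as well, though few of their members passed. In the list of the glyoxylate shunt and acetate use, 2 of 12 rose (3 adjusted over the list alone, 5 with the block), aceB (3.63 ± 0.66, adjusted p = 0.00226) and aceA (10.5-fold, adjusted p = 0.000866). The list had a camera adjusted p of 0.00224, and an adjusted p of 0.8 with an estimated correlation. In the TCA cycle 3 of 15 rose (3 adjusted over the list alone), namely gltA for citrate synthase (2.47 ± 0.74, adjusted p = 0.0441), fumC (2.29 ± 0.53, adjusted p = 0.0106) and acnA (2.28 ± 0.65, adjusted p = 0.0357). The TCA mean was 1.95, 0.94 and -0.24 in the 3 replicates, and camera's adjusted p of 0.00877 became an adjusted p of 0.878 with an estimated correlation. Of 16 glycolysis genes 1 rose, pfkB for the minor phosphofructokinase (1.92 ± 0.44, adjusted p = 0.00923; 2 adjusted over the list alone, 3 with the block), with camera at 0.0472 (0.0775 with no pseudocount) and an adjusted p of 0.932 with an estimated correlation. None of the 6 autoinducer-2 uptake genes passed (5 adjusted over the list alone, 1 with the block), with a mean of 2.07 ± 1.45. The list passed in camera (adjusted p = 0.00354), and had an adjusted p of 0.788 with an estimated correlation.

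Genes for making protein went down over the same span. All 54 ribosomal protein genes had a negative mean change, with an average of -2.41 ± 0.81 (SD over 3 replicates), and 9 of them fell (42 adjusted over the list alone, 52 with the block). The largest were rpsT (-3.56 ± 0.86, SE, adjusted p = 0.0133), rpsF (-3.42 ± 0.93, adjusted p = 0.0288) and rpsI (-3.31 ± 0.97, adjusted p = 0.0425). The list's adjusted p was 3.24e-21 in camera, and the adjusted p was 0.641 with an estimated correlation. Of 32 translation factor and aminoacyl-tRNA synthetase genes 4 fell (5 adjusted over the list alone; 18 fell and 1 rose with the block), including infA, for initiation factor IF1 (-3.18 ± 0.90, adjusted p = 0.0347), prfC (-2.09 ± 0.51, adjusted p = 0.0149) and tsf, for elongation factor Ts (-2.47 ± 0.75, adjusted p = 0.0477). The list's mean was -1.05 ± 0.29, with camera at 9.54e-07 and an adjusted p of 0.878 with an estimated correlation. Among 16 genes of RNA polymerase and DNA topology 1 fell, the termination factor rho (-1.92 ± 0.52, adjusted p = 0.0288; 1 adjusted over the list alone, 10 with the block), with a list mean of -1.30 ± 0.42, camera at 2.51e-05 and an adjusted p of 0.8 with an estimated correlation. Of 34 genes for DNA replication and cell division 1 fell, dnaX (-2.27 ± 0.46, adjusted p = 0.00424; 1 adjusted over the list alone, 11 with the block), with camera at 0.00324 and an adjusted p of 0.932 with an estimated correlation.

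The lists of respiration, fatty acid synthesis, nucleotide synthesis and cold shock were lower on average too, though most members of each did not pass. Of 28 genes for aerobic respiration and ATP synthase 10 fell (13 adjusted over the list alone, 14 with the block), with atpD (-2.93 ± 0.64, adjusted p = 0.00705), atpH (-2.88 ± 0.75, adjusted p = 0.0213) and atpC (-2.74 ± 0.80, adjusted p = 0.0415) in front. These 3 are all ATP synthase genes. The mean of the list was -1.14 ± 0.30, with 7 of the 28 genes above 0 and camera at 1.86e-05. In fatty acid synthesis 2 of 16 fell (2 adjusted over the list alone, 6 with the block), accC (-2.87 ± 0.73, adjusted p = 0.0189) and accB (-2.45 ± 0.70, adjusted p = 0.0361), with camera at 0.00224. In purine and pyrimidine synthesis 2 of 25 fell (0 adjusted over the list alone; 8 fell and 1 rose with the block), prs (-2.22 ± 0.66, adjusted p = 0.0431) and purM (-1.53 ± 0.46, adjusted p = 0.0493), with camera at 0.00113. The adjusted p was 0.878 with an estimated correlation for each of these 3 lists. Of 12 cold shock genes 4 fell (8 adjusted over the list alone, 8 with the block), with cspF (-3.43 ± 0.50, adjusted p = 0.000896) beside cspB and cspG, and 1 rose, cspD (4.29 ± 1.03, adjusted p = 0.0126), whose product is known from stationary phase as an inhibitor of replication. For cold shock camera gave an adjusted p of 0.000292, and the adjusted p was 0.641 with an estimated correlation.

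Flagella and chemotaxis genes differed between replicates in this comparison. Of 52 genes 7 fell and none rose (11 fell adjusted over the list alone, while 15 fell and 3 rose with the block), with fliO (-2.97 ± 0.74, adjusted p = 0.0162), fliQ (-2.80 ± 0.71, adjusted p = 0.0176) and fliP (-2.59 ± 0.72, adjusted p = 0.0324), all parts of the flagellar export gate, in front. The list mean was -0.60, 0.29 and -1.41 in replicates 1, 2 and 3. In camera the adjusted p was 0.0235, 0.149 with the block, 0.0534 on ranks and 0.0682 after quantile normalisation, with an adjusted p of 0.935 with an estimated correlation. None of 19 heat shock and protease genes passed (0 adjusted over the list alone; 6 fell and 1 rose with the block), with a list mean of -0.53 ± 0.19, camera at 0.045 (0.0789 with no pseudocount) and an adjusted p of 0.932 with an estimated correlation. For phosphate and nitrogen starvation 3 of 33 rose (7 with the block), and camera gave 0.0558, or 0.0497 with the block and an adjusted p of 0.646 with the block and an estimated correlation. Camera called no shift in the remaining lists. These are fimbriae and curli (adjusted p = 0.853, where 1 of 16 rose in both fits), anaerobic respiration and fermentation (0.956, where 1 of 42 rose, and 2 rose and 1 fell with the block), amino acid catabolism (0.678, where 4 of 26 rose, and 4 rose and 3 fell with the block) and alternative sugar and glycerol use (0.725, where 3 of 67 rose, and 16 with the block). They also include amino acid biosynthesis (0.738, where 1 of 80 rose and 1 fell, and 7 rose and 5 fell with the block), iron uptake (0.287, where 2 of 34 rose, and 5 rose and 2 fell with the block) and oxidative stress and the SOS response (0.224, where 1 of 26 rose, and 4 with the block). Mean and median differed in sign for amino acid catabolism (0.29 and -0.09) and for fimbriae and curli (0.04 and -0.02), and for alternative sugars the mean was -0.10 while camera's direction was upward.

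**Figure D2:**
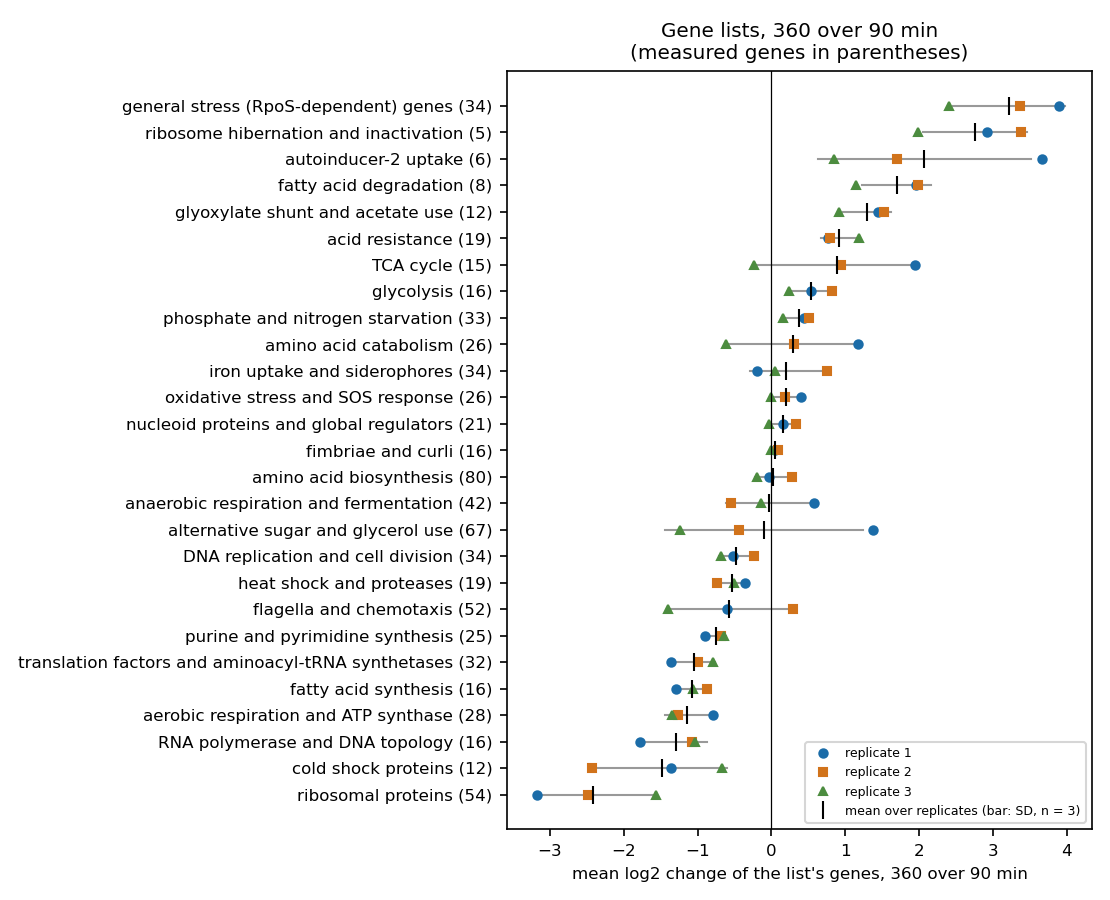
Mean log2 change from 90 to 360 min of the measured genes of each of the 27 lists (x axis), with one symbol per replicate, a tick for the mean and a bar for the SD over 3 replicates. RpoS-dependent genes lie at a mean of 3.22 and ribosomal proteins at -2.41, while the symbols of flagella and chemotaxis spread from -1.41 to 0.29.

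The profiles of replicate 1 at 150 and 240 min lay closer to its 90 min profile than those of the other replicates did to theirs. Each array was placed on the line from the 90 min profile (0) to the 360 min profile (1) of its own replicate, along the mean change of the other replicates, with arrays scaled to one median. At 150 min replicates 2 and 3 lay at 0.33 and 0.31, and replicate 1 at 0.05. At 240 min replicates 2 and 3 lay at 0.92 and 0.97, and replicate 1 at 0.21, with bootstrap SDs over genes of 0.00911 to 0.0174. Each position rests on 1 array, so these SDs do not measure the spread between arrays of one time. The difference of replicate 1 from the others bears on each interval between neighbouring times below.

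**Figure D3:**
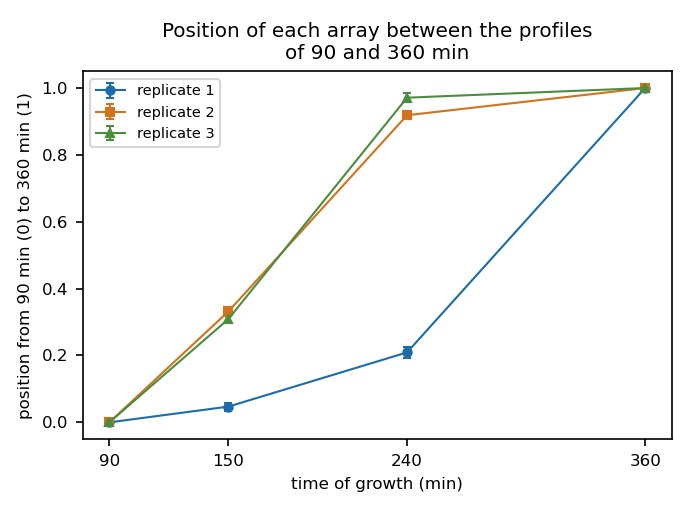
Position of each array between the 90 min profile (0) and the 360 min profile (1) of its own replicate against time of growth in min, with one line per replicate and bars for the bootstrap SD over genes. The bars do not measure the spread between arrays. At 240 min replicate 1 lies at 0.21, and replicates 2 and 3 lie at 0.92 and 0.97.

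From 90 to 150 min, within logarithmic growth, 4 genes were at least 2-fold higher in every replicate. They are the hibernation genes rmf and sra, the stress gene dps and cspD of the cold shock list. Levels of rmf were 2.90 ± 1.10 higher on the log2 scale (SE, n = 3 per time), those of sra 2.27 ± 0.84, of dps 2.23 ± 0.93 and of cspD 1.90 ± 1.03. Other named genes with means as high, such as tnaA (2.76; 1.47, 5.96 and 0.85 in the 3 replicates) and mglB (2.61; 3.02, 3.92 and 0.89), did not reach 2-fold in replicate 3, and elaB (2.32; 0.62, 3.90 and 2.45) did not in replicate 1. The ferric citrate uptake genes fecA (-1.62 ± 0.57) and fecB (-1.62 ± 0.52) were at least 2-fold lower in each. None of the 3646 genes passed limma's test (65 at an unadjusted p under 0.05), nor with the replicate block (226 unadjusted, smallest adjusted p 0.537 for rmf). Turning the signs of replicate 1, 2 or 3 gave 10, 1 and 28 genes with such consistent changes in place of 6. Leaving out the 90 min array of replicate 1 gave 1 call (2 with the block), and leaving out all of replicate 1 gave 7 (32 with the block).

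Camera called lists in this interval at the preset correlation, though none of their members passed. Neither camera with an estimated correlation nor fry called any list. TCA cycle genes were higher on average by 1.14 ± 0.63 (SD over 3 replicates), with all 15 means above 0 and the largest in mdh, for malate dehydrogenase (1.76 ± 0.81, SE). Iron uptake genes had a mean of -0.48 ± 0.18, with 2 of 34 above 0 (0 adjusted over the list alone, or 8 lower when the block is added to that), and RpoS-dependent genes a mean of 0.91 ± 0.58, with the largest in elaB (2.32 ± 0.89). Camera's adjusted p was 1.26e-14 for the TCA cycle, 3.69e-16 for iron uptake, 1.89e-12 for RpoS-dependent genes and 1.55e-05 for cold shock proteins (mean -0.54). In all 4 the adjusted p was 0.641 with an estimated correlation. Hibernation genes had a mean of 1.18 (camera adjusted p = 0.00613, or 0.0907 on ranks, and an adjusted p of 0.644 with an estimated correlation; 2 members adjusted over the list alone). Ribosomal proteins (-0.48, 1.92e-08), RNA polymerase and DNA topology (-0.35, 0.00113), heat shock and proteases (-0.33, 0.000362) and the glyoxylate shunt and acetate use (0.61, 0.00997) were also called, with an adjusted p of 0.878 with an estimated correlation in each. For ribosomal proteins the adjusted p was 0.0673 after quantile normalisation. Flagella and chemotaxis (0.53, 0.00275), translation factors (-0.12, 0.0338, or 0.0548 with no pseudocount) and alternative sugar and glycerol use (0.16, 0.0427, or 0.0526 with the block) had an adjusted p of 0.932 with an estimated correlation. Replicates differed in sign for flagella (1.5, 1.45 and -1.34), alternative sugars (1.14, -0.08 and -0.58) and heat shock (-0.06, -1.05 and 0.13). With the block camera also called glycolysis (0.29, 0.00704, and an adjusted p of 0.602 with an estimated correlation) and fatty acid synthesis (-0.18, 0.0286, and an adjusted p of 0.646 with an estimated correlation).

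From 150 to 240 min, into late logarithmic phase, genes of melibiose use were among those higher in every replicate. Levels of melA were 2.94 ± 0.70 higher (SE, n = 3 per time) and those of the transporter gene melB 2.41 ± 0.50 higher. Among the 40 genes at least 2-fold higher in each replicate were also sra (2.42 ± 0.84), ytfQ (2.84 ± 0.87), rmf (2.52 ± 1.10), fadH (1.82 ± 0.50), the aldehyde dehydrogenase gene aldA (2.30 ± 0.71) and the thiosulfate uptake gene tsuB (2.06 ± 0.47). The 8 genes at least 2-fold lower in each included cspB (-2.15 ± 0.70), cspF (-1.93 ± 0.50), cspG (-1.66 ± 0.80), secG (-1.57 ± 0.85), dusA (-1.25 ± 0.47), atpI (-1.24 ± 0.57), upp (-1.18 ± 0.65) and the DNA polymerase gene dnaE (-1.05 ± 0.60). None passed limma's test (160 at an unadjusted p under 0.05), nor with the block (466 unadjusted, smallest adjusted p 0.0999). Turning the signs of replicate 1, 2 or 3 gave 7, 1 and 0 genes in place of 48. Without the 240 min array of replicate 1, 18 genes passed, 17 higher and 1 lower (160 with the block), and without all of replicate 1, 6 passed (200 with the block).

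Several lists moved less in replicate 1 than in the others in this interval. Autoinducer-2 uptake genes had a mean of 1.76 ± 1.49, from 0.06 in replicate 1 to 2.81 and 2.43 in replicates 2 and 3, with lsrF (2.59 ± 0.91) and lsrD (2.36 ± 0.80) highest and 3 of 6 passing when adjusted over the list alone (0 when the block is added to that). Ribosomal protein genes had a mean of -0.24 in replicate 1, against -1.97 and -1.17 in the others, and RpoS-dependent genes had 0.60 against 1.74 and 1.22. Fatty acid degradation genes had a mean of 1.05 ± 0.61 (5 of 8 adjusted over the list alone) and hibernation genes 1.33 ± 0.11 (0 adjusted over the list alone, 3 when the block is added to that). Camera's adjusted p was 4.35e-05 for autoinducer-2 uptake, 1.16e-16 for RpoS-dependent genes, 1.55e-05 for fatty acid degradation, 0.00155 for hibernation, 0.000647 for acid resistance (0.46) and 0.000668 for cold shock (-0.71; 2 adjusted over the list alone). In all 6 the adjusted p was 0.641 with an estimated correlation. For ribosomal proteins it was 3.24e-17, with an adjusted p of 0.702 with an estimated correlation, and for the TCA cycle 0.000176, with an adjusted p of 0.8 with an estimated correlation. The TCA mean ran the other way, at 1.41 in replicate 1 against 0.32 and 0.22. So did those of amino acid catabolism (0.97 against 0.14 and 0.19) and alternative sugar and glycerol use (0.65 against 0.07 and 0.05). Replicates differed in sign for acid resistance (-0.11, 0.38 and 1.11), the glyoxylate shunt (0.38, -0.06 and 0.99) and phosphate and nitrogen starvation (-0.05, 0.51 and 0.29). Translation factors (-0.49, 2.68e-05), RNA polymerase and DNA topology (-0.53, 0.00111), purine and pyrimidine synthesis (-0.49, 0.000155), amino acid catabolism (0.43, 0.014) and the glyoxylate shunt (0.44, 0.0364) had an adjusted p of 0.878 with an estimated correlation. In the glyoxylate list aceB (2.22 ± 0.66) and aceA (1.95 ± 0.49) stood highest (2 adjusted over the list alone, 3 when the block is added to that), and in amino acid catabolism astC (3.27 ± 0.78; 1 adjusted over the list alone). Quantile normalisation moved the glyoxylate list, and phosphate and nitrogen starvation, to an adjusted p of 0.054 each, and on ranks the glyoxylate list had 0.218 and amino acid catabolism 0.0507. DNA replication and cell division (-0.25, 0.00461), alternative sugar and glycerol use (0.26, 0.00671), fatty acid synthesis (-0.41, 0.0221) and phosphate and nitrogen starvation (0.25, 0.0223) had an adjusted p of 0.932 with an estimated correlation.

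The samples of 240 and 360 min are described as late logarithmic and early stationary. By their profiles, replicates 2 and 3 already lay at 0.92 and 0.97 of the way to 360 min at 240 min, and replicate 1 at 0.21. From 240 to 360 min, genes for the use of tryptophan and sugars were among those at least 2-fold lower in every replicate. Levels of tnaA, for tryptophanase, differed by -3.98 ± 1.28 (SE, n = 3 per time), with -4.22, -3.80 and -3.92 in the 3 replicates, and those of tnaB, for the tryptophan carrier, -1.90 ± 0.48. Means as low were also found for flagellar genes, such as flgB (-2.40; -5.63, 0.05 and -1.62 in the 3 replicates). The maltose uptake genes malE (-3.19 ± 1.28), malK (-2.17 ± 1.24) and lamB (-2.08 ± 1.24), the galactose uptake genes mglC (-2.15 ± 0.46) and mglA (-2.05 ± 0.62) and mepS (-2.36 ± 0.73) were also among the 22 genes at least 2-fold lower in each replicate. The 5 at least 2-fold higher in each were yohC (2.81 ± 0.59), the glutaredoxin-like nrdH (1.60 ± 0.45), the phage shock gene pspC (1.46 ± 0.37), the tryptophan permease gene mtr (1.38 ± 0.48) and the enterobactin synthesis gene entF (1.31 ± 0.26). None of the 3646 genes passed limma's test (149 at an unadjusted p under 0.05), nor with the block (468 unadjusted, smallest adjusted p 0.0645 for entF). Turning the signs of replicate 1, 2 or 3 gave 11, 0 and 2 genes in place of 27. Without replicate 1, 1 gene passed (18 with the block), and a fit on the 6 arrays alone called 3.

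The lists of motility, respiration and the TCA cycle had lower means at 360 than at 240 min, and camera called them at the preset correlation. Flagella and chemotaxis genes had a mean of -1.24 ± 1.09 (SD over 3 replicates), with all 52 below 0, and -2.41, -0.26 and -1.06 in replicates 1, 2 and 3. Aerobic respiration and ATP synthase genes had a mean of -0.99 ± 0.47, with atpD at -1.68 ± 0.64 (SE; 0 of 28 adjusted over the list alone, 16 when the block is added to that), and the TCA cycle -0.90 ± 0.28, with sucD at -1.74 ± 0.65. Iron uptake genes had a mean of 0.61 ± 0.37, with entH at 1.67 ± 0.42 and 4 of 34 passing when adjusted over the list alone (10 higher and 1 lower when the block is added to that). Camera's adjusted p was 3.42e-15 for respiration, 4.26e-07 for the TCA cycle, 9.45e-15 for iron uptake, 8.02e-19 for RpoS-dependent genes and 0.000167 for acid resistance (0.41). In all 5 the adjusted p was 0.641 with an estimated correlation. For flagella it was 6.03e-15, with an adjusted p of 0.741 with an estimated correlation. RpoS-dependent genes had a mean of 3.04 in replicate 1 against 0.31 and 0.02 in replicates 2 and 3, and ribosomal proteins -2.63 against 0.20 and -0.00. Ribosomal proteins (6.96e-08), amino acid catabolism (-0.61, 0.00747; 1 adjusted over the list alone, 0 when the block is added to that) and fatty acid degradation (0.47, 0.0158, or 0.0589 with the block) had an adjusted p of 0.878 with an estimated correlation. Translation factors (-0.44, 0.00101), RNA polymerase and DNA topology (-0.41, 0.0388), alternative sugar and glycerol use (-0.52, 0.000713; 1 adjusted over the list alone, 2 when the block is added to that), purine and pyrimidine synthesis (-0.35, 0.0131) and fatty acid synthesis (-0.48, 0.0441) had an adjusted p of 0.932 with an estimated correlation. With no pseudocount, RNA polymerase and fatty acid synthesis had an adjusted p of 0.085 each. Replicates differed in sign for fatty acid degradation (1.72, -0.19 and -0.12), RNA polymerase (-1.24, 0.11 and -0.11), purine and pyrimidine synthesis (-0.93, 0.15 and -0.27) and acid resistance (0.79, 0.56 and -0.12). With the block camera also called DNA replication and cell division (-0.21, 0.0491, and an adjusted p of 0.633 with an estimated correlation).

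The comparison of 240 with 90 min was added after the values were seen, since no gene passed between neighbouring times. It found 17 changed genes, 14 higher and 3 lower, against 441 at an unadjusted p under 0.05 and 173 with the block (121 and 52). The melibiose genes melA (4.68 ± 0.70, SE, n = 3 per time, adjusted p = 0.0102) and melB (2.91 ± 0.50, adjusted p = 0.0223) rose, as did cysK, for cysteine synthase (2.52 ± 0.46, adjusted p = 0.0232), and sra (4.69 ± 0.84, adjusted p = 0.0232). The other rises were in ytfR, ytfQ, argT (b2310), rmf, aldA, astC, the thioesterase gene fadM (b0443), aceA, hdhA (b1619) and ychH (b1205). All 3 falls were in cold shock genes, cspF (-3.12 ± 0.50, adjusted p = 0.0133), cspB (-3.56 ± 0.70, adjusted p = 0.0368) and cspH (-2.74 ± 0.58, adjusted p = 0.0449). The count was 162 without the 240 min array of replicate 1, 0 without the 90 or the 240 min array of replicate 2, 1 without the 240 min array of replicate 3 and 4 without the 90 min array of replicate 1. It was 29, 36 and 33 without the 150 min array of replicate 1, 2 or 3, and 38 without the 360 min array of replicate 3. With the block the count of 173 became 3 without the 90 min array of replicate 2, 2 without the 240 min array of replicate 2 or of replicate 3, 48 without the 90 min array of replicate 1, 572 without the 240 min array of replicate 1 and 575 without the 360 min array of replicate 1. It also fell to 65, 24 and 73 without the 150 min array of replicate 1, 2 or 3 and to 26 without the 360 min array of replicate 2. All of replicate 1, 2 or 3 left out gave 609, 0 and 42.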

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

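The test against phage and plasmid probe sets was chosen after it was seen that many probe sets hold values for replicate 3 alone. On its 4 arrays 669 of 2886 intergenic probe sets (23.2%) lay above the 95th percentile of 59 probe sets for phage and plasmid genes, a level of 66.6 to 111. The same held for 248 of 623 gene probe sets (39.8%). With 1 array per time these values allow no test. Among those above that level, 12 intergenic probe sets were at least 4-fold higher at 360 than at 90 min and 40 at least 4-fold lower, while 15 gene probe sets were higher and 5 lower.

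Genes of pathways described above are among the probe sets with values for replicate 3 alone. Signals of astA, in the arginine degradation operon of astC, were 111.5, 300.2, 1878.5 and 2017.5 at 90, 150, 240 and 360 min, and those of astB went from 119.1 to 1387.2. Those of lsrB, for the binding protein of autoinducer-2 uptake, were 42.5, 154.5, 3723 and 283.2, with the top at 240 min, and lie below that level at 90 min. Among the genes above that level the largest gains were in yebV, from 101.4 to 5445.4, and yegP, from 88.5 to 3796.8, both of unknown function, and these genes were chosen after the values were seen.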

How the results depend on the processing

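Leaving out a whole replicate, and quantile normalisation with the block, were chosen after the results were seen, and the other alternatives before. No alternative turned the direction of a call, and the cause of the moves below was not tested. Of 3646 genes, 173 changed over the 4 times, and this count was 461 with quantile normalisation, 430 with one median, 422 with one 75th percentile, 677 with the replicate block, 97 with no variance trend, 507 with array weights, 832 with quantile normalisation and the block, and 51 to 288 with 1 array left out. For 360 against 90 min (318 genes) the same settings gave 794, 795, 793, 1008 (block), 756 (array weights), 1169 (quantile and block), and 141 to 392 with 1 array left out. Leaving out replicate 1, 2 or 3 gave 104, 0 and 2 over the 4 times and 130, 62 and 278 for 360 against 90 min. Between neighbouring times (0 genes each), leaving out replicate 1 gave 7, 6 and 1, leaving out replicate 2 or 3 gave 0 each, and leaving out 1 array gave 0 to 1, 0 to 18 and 0. The 6 arrays of 240 and 360 min alone gave 3. For 240 against 90 min (17 genes) the count was 11 with quantile normalisation, 58 with no pseudocount, 45 and 6 with the 10th and 50th percentile as pseudocount, 38 and 35 with the dimmest genes left out, 173 with the block, 6 with no variance trend, 47 with robust variance, 41 with array weights, 104 on 6 arrays, 116, 0 and 1 without replicate 1, 2 or 3, 395 with quantile normalisation and the block, and 0 to 162 with 1 array left out. The fis change was -2.93 with the block (adjusted p = 0.0122) and on 6 arrays (5.31e-05), -3.19 with array weights (0.0386), -2.80 with quantile normalisation and the block (0.0115), and -1.80 to -3.61 with 1 array left out. On 6 arrays limma gave every gene the spread of the trend, 0.748 at the level of fis, where its own SD was 1.41, so that p is too small. Of 108 list tests 61 were called with the preset correlation, 0 with an estimated correlation, 0 with fry, and 0 with the block and an estimated correlation. Intergenic probe sets could not be added to the fit, since they hold values for replicate 3 alone.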

Other observations

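Of the tests in this part, those of exchanged labels and of the array version were written after the pattern was seen, and the others before, though the comparison of 240 with 90 min was itself added late. Genes for maltose and tryptophan use differed between replicates early in growth, and these genes were picked after the values were seen. Signals of malE, the maltose-binding protein, were 109 in replicate 1 at 90 min and 13566.8 and 6739.9 in replicates 2 and 3, and those of lamB, the maltose porin, were 145.4, 13309.3 and 7450.5. In replicate 1 malE reached 9730.2 at 240 min. Signals of tnaA at 150 min were 266.7, 33245.6 and 6835.4 in replicates 1, 2 and 3. The lsrF gene of autoinducer-2 breakdown stood at 121.3 in replicate 1 at 240 min against 4228.5 and 1826.8 in the others, and at 360 min at 5176 against 925.5 and 166.7.

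Replicate 1 at 240 min lies nearer the 90 min profile than replicates 2 and 3, at a position of 0.21 against 0.92 and 0.97. An exchange of its 150 and 240 min labels is argued against, since its 240 min array lies 0.162 further along than its 150 min array. Each position rests on 1 array, so the spread between arrays is not known here. The older array version is argued against too, since replicate 2, on the same version, lies 0.709 further along at 240 min. Among 2983 genes far below the ceiling of the arrays the gap to the nearer replicate stays at 0.673, so saturated signals are not the cause. A later passage of that culture through growth may be the cause, and optical densities for each sample would test it. The control probe set AFFX-CreX-3, at 8.7 to 10.4 on the arrays of replicate 1, also set that replicate apart. Whether this bears on the position was not tested.

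Log2 changes between 90 and 360 min are smaller in replicate 3, with an SD over genes of 0.94 against 1.45 and 1.26, a ratio of 0.693 to the mean of the others. Scaling to one median gave a ratio of 0.781 (bootstrap SD 0.0117), where a fixed offset on a lower scale was to give at least 0.9 and its absence 0.8 or less. This argues against the offset as the whole cause, narrowly, since the value lies under 0.8 by more than 1 of its SDs and less than 2, and the margin of 1 was settled after the value was seen. With no pseudocount, and so no added offset, the ratio was still 0.817 (bootstrap SD 0.0137), over 0.8 and short of 0.9. The smaller changes of replicate 3 thus remained without the offset, which can account for a part at most. Among genes far below the ceiling of the arrays the ratio was 0.836, between the bounds, so saturated signals may contribute and stay open.

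Genes near the replication origin were lower at 360 than at 90 min relative to genes far from it. Distance was counted in gene order. Without ribosomal protein and translation genes, Spearman's rho between change and distance was 0.089, 0.177 and 0.185 in the 3 replicates, with a mean of 0.150. Of 931 rotations of the origin, 13 gave as large a mean, the highest 0.151. Neighbouring rotations give nearly the same distances, so this is not a share of independent draws. With all genes the mean rho was 0.161, and 30 of 931 rotations reached it. The median change was -0.20 for 811 genes near the origin and 0.11 for 564 genes far from it. The pattern is consistent with a higher copy number of origin-near genes during fast growth, though position may also stand for function. Without any gene of the 27 lists the mean rho was 0.156 (25 of 931 rotations), and sequencing of genomic DNA at the same times would test it.

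Regrouping the arrays asks whether such counts arise by chance. Over the 4 times, 4 of 100 assignments, the real one included, gave at least 173 genes, and the highest other gave 484. That one set the 3 arrays of replicate 2 after 90 min as one group and those of replicate 3 as another, so its groups follow the replicate number, and the cause of that was not tested. Assignments with 337 and 240 genes also passed the real count. The one with 337 put at most 2 arrays of one replicate in a group, so the replicate number does not describe it. With times reordered within replicates 1 of 100, the real one, reached 677 genes, and the highest other gave 370. A share of 1 in 100 is the smallest this test could give. A chance order of the times is thus unlikely for these 12 arrays, but not excluded. The count of 677 became 69 without the 90 min array of replicate 2, so it rests on single arrays. Splits of 6 arrays number 10, too few for a share under 0.05. For 360 against 90 min 1 of 10 reached the real 318 (highest other 0), and for 240 against 90 min 1 of 10 reached 17 (highest other 1). Between neighbouring times all 10 splits had to reach the real count of 0, so the share says nothing there. The highest others were 6 for 150 against 90 min, 29 for 240 against 150 min and 7 for 360 against 240 min.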
